A study of Homo sapiens with 4 samples.

How the data were processed

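The study used Flp-In T-REx cells (293TREx in the labels) with a tetracycline-dependent EP400NL gene. It has 4 libraries, 2 untreated and 2 treated with 1 µM tetracycline for 12 h, grouped by the treatment in their labels. Per the labels' protocols, total RNA with a RIN above 7 was depleted of ribosomal RNA, and stranded libraries were made with random primers and sequenced from both ends on a NovaSeq. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to hg38 with STAR, counted per gene with featureCounts and compared with DESeq2; no versions are given.

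One table, the authors' DESeq2 result, was used. Per the file headers, it gives the authors' mean normalized count of each gene over all libraries, which follows from the scaling of counts between libraries that DESeq2 does. It also holds the authors' deposited log2 fold change with its standard error, and the values show that these are shrunken: the median ratio of the estimate over its standard error to the z of the p-value was 0.622. The authors' deposited p-value and adjusted p are those of their DESeq2 test, per the file headers and the submitters' processing notes. The table has 20398 genes, 17024 with a symbol and 13684 with an adjusted p, which begin at a mean normalized count of 41.2. The smallest adjusted p implies an adjustment over 13702 genes, of which 18 are not analysed here. The smallest mean in the table is 2.02. The header does not name the direction, and positive values were read as higher with tetracycline because EP400P1 is positive.

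No values per library were used here, so the depth of each library, the spread of single genes between libraries and an estimate of the correlation between genes could not be had. Precision is therefore that of the authors' standard errors, and genes below a mean of 41.2 have a p-value but no adjusted p in the authors' deposited table. Other ways of splitting the 4 libraries, and tests for an outlying library, were not run for the same reason.

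A gene counts as changed when its adjusted p in the authors' deposited table is under 0.05, and the verbs rose and fell are kept for such genes. Gene lists were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 1076 list entries, 1004 were found by symbol or synonym. Each p-value was turned into a z with the sign of the log2 fold change, and cameraPR of limma 3.58.1 tested each list against all other genes with a mean normalized count of at least 10. The preset correlation between genes was 0.01, since no estimated correlation could be had without values per library. The list p-values were adjusted by Benjamini-Hochberg over the 28 lists that could be tested, and the blood cell markers could not. The shift of a list is the mean z of its members minus that of all other genes, and its SE follows from the preset correlation. Members were also adjusted over the list alone, which is a different question from the adjustment over all genes.

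The genes named in the text are EP400P1 and EP400, the 10 genes with a symbol, a mean of at least 50 and the largest log2 fold change each way, and up to 4 members of each list with the smallest adjusted p. Also named, whatever their values, are ODC1, AMD1, SRM, SMS, SAT1, OAZ1 and AZIN1 of the polyamine list, the regulators PPARGC1A, NRF1 and TFAM, and MYC and CD274. Other genes, MT-CO1 and MT-ATP8 among them, and all members that make up a small count, were chosen after their values were seen. Some genes that the rule names are not used here.

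Alternatives for the gene counts were other thresholds on the adjusted p and the fold change, other minimum counts with a new adjustment, Bonferroni, an empirical null with the spread of z taken from its median absolute deviation, and centring on the median gene. For the lists they were preset correlations of 0.05 and 0, ranks or log2 fold changes in place of z, other minimum counts, a protein-coding background, and 10000 random lists matched on mean count in 20 bins. Because fold change was seen to move with count and length, further alternatives were added after the data were seen. These were z corrected by splines with 6 knots for mean count, exonic length and GC content, random lists matched on count (10 bins) and length (5 bins), and a gene count over protein-coding genes only. Random lists were drawn gene by gene, so their p-values allow for no correlation between members, while those of cameraPR do. Lengths, GC content, gene classes and coordinates came from GENCODE 29 on GRCh38, for 98.8% of the 17380 genes of the list tests. The exonic length covers every annotated exon of a gene, so it can exceed that of the expressed transcript.

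The list tests were tested on simulated data first. For the 17380 genes of the comparison of tetracycline with untreated, cameraPR recovered 82.7% of lists shifted by 1 z in 100 draws and called 0.364% of unshifted lists. The simulated z were independent between genes and held no trend with count, length or GC. The 0.364% is therefore no measure of false calls among lists whose genes move together or follow such a trend. A list of 26 genes was recovered in 56% of draws, so small lists that did not pass may still be shifted. In the same comparison, the spline correction was tried on a simulated trend in mean count, with none in length or GC. It gave 0.895 for a list simulated with a shift of 1, and took the cytosolic ribosomal list, simulated with the trend only, from 1.43 to -0.129.

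Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Genes without a p-value were left out of the list tests, and genes without an adjusted p out of the gene counts.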

Results

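Flp-In T-REx cells derive from the human embryonic kidney line HEK293 and carry a Tet repressor and a recombination site that takes 1 tetracycline-dependent transgene. Here the transgene was EP400NL, and the stated purpose was to find the genes whose expression depends on it. The title names polyamine synthesis and mitochondrial biogenesis in cell growth. EP400NL is the older name of EP400P1, a transcribed copy of part of EP400, which encodes the large ATPase of the TIP60 chromatin complex. Total RNA depleted of ribosomal RNA was sequenced from 2 untreated libraries and 2 libraries of cells given 1 µM tetracycline for 12 h. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Cells given tetracycline without the EP400NL construct were not analysed here, so a response to the antibiotic and a response to EP400NL are not separated. Values per library were not used here, and the depth of each library is unknown. The mean normalized counts of the 20398 genes summed to 26332678.

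EP400NL itself is in the table as EP400P1. This gene (ENSG00000185684, chromosome 12, 132084283 to 132131639, plus strand, GRCh38, annotated as a transcribed unprocessed pseudogene) had the largest fold change among the genes with an adjusted p. Its log2 fold change in the authors' deposited table was 3.39 (SE 0.15, adjusted p = 3.53e-109), which is 10.5-fold, at a mean normalized count of 2395. The header of that table does not name the direction of the comparison, and the positive value for EP400P1 is the reason why positive values are read here as higher with tetracycline, so this value is no test of the induction. EP400 itself lies just upstream on the same strand (chromosome 12, 131949920 to 132081102) and stood at -0.20 (SE 0.21, adjusted p = 0.236) in the authors' deposited table, so it did not pass. Reads from the parts that the 2 genes share, and from the transgene, could have been counted for either or for neither, so both values are uncertain.

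With tetracycline, 1341 genes were higher and 569 were lower, out of 13684 with an adjusted p. Most shifts were small. The median log2 fold change was 0.40 among the genes that rose and -0.57 among those that fell, and only 5 genes rose and 48 fell by 1 or more. After EP400P1, the largest rises among genes with a mean count of at least 50 in the authors' deposited table were those of ACTA2, the smooth muscle actin, at 1.37 (SE 0.32, adjusted p = 0.000147), ZCCHC12 at 1.17 (SE 0.13, adjusted p = 4.26e-16), and HSPA8, the constitutive HSP70 chaperone, at 1.06 (SE 0.13, adjusted p = 1.69e-13). ETV5, an ETS transcription factor, rose by 1.06 and GBE1, the glycogen branching enzyme, by 0.97 in the authors' deposited table. The authors' deposited table also had POLE4, a subunit of DNA polymerase epsilon, at 0.95, the histone gene H2AC21 at 0.91, the kinesin KIF9 at 0.90, and ADI1, an enzyme of methionine salvage, at 0.89. All of these passed, with adjusted p from 4.26e-16 (ZCCHC12) to 0.00514 (KIF9) in the authors' deposited table.

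With the same minimum, the deepest falls were in genes of low mean count. STUM stood at -1.99 (SE 0.32, adjusted p = 2.29e-08) in the authors' deposited table, at a mean count of 114. VSTM2B at -1.36 and HSPG2, which encodes the matrix proteoglycan perlecan, at -1.33 were also among them in the authors' deposited table. Further such genes were NYNRIN at -1.29, the semaphorin SEMA3G at -1.28, TMEM255A at -1.27, RNF165 at -1.26, the sarcomere protein MYOM2 at -1.25 and the secreted guidance factor SLIT3 at -1.23, again in the authors' deposited table. Their adjusted p in the authors' deposited table lay between 5.82e-09 (MYOM2) and 0.00175 (SLIT3). When the spread of z over all genes, 1.85, was taken as chance in place of 1, only 3 genes passed, EP400P1, ZCCHC12 and HSPA8. A correction for mean count, exonic length and GC content, added after the data were seen, left 151 genes higher and 147 lower, so the share of higher genes went from 70.2% to 50.7%. With it 74 of the named genes stopped passing, so the single rises and falls given here hold for the deposited adjusted p.

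**Figure D1:**
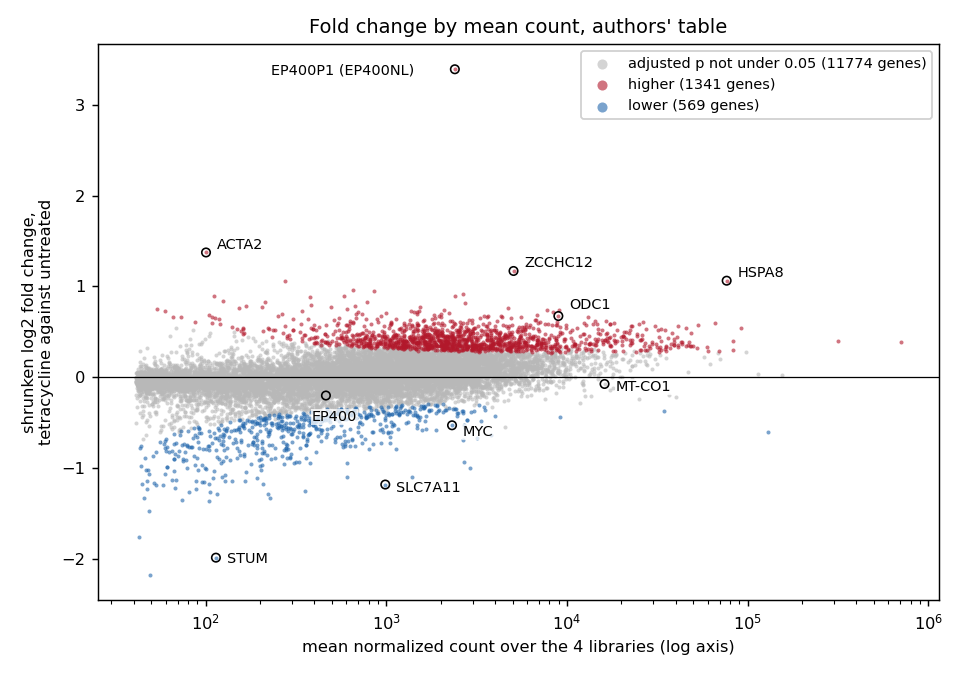
Mean normalized count over the 4 libraries (log axis) against the shrunken log2 fold change, tetracycline against untreated, both from the authors' deposited table, for the 13684 genes with an adjusted p. Red points are the 1341 genes that rose, blue points the 569 that fell and grey points those that did not pass; circles mark 10 genes, and the genes that fell lie mostly at lower counts than those that rose.

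Fold change moved with the abundance and the length of the transcript. Genes that rose had a median mean count of 2455 and a median exonic length of 3528 bases, against 317 and 7583 for genes that fell. Across 13635 genes, which are not independent replicates, Spearman's rho of the log2 fold change was 0.456 with mean count, -0.274 with exonic length and -0.181 with GC content. Among protein-coding genes in the top decile of mean counts, 425 rose and 2 fell, while in the lowest decile 6 rose and 83 fell. Splines of the 3 properties together took up 40.6% of the variance of z. Values on RNA quality and on the removal of ribosomal RNA in each library were not used here, so a difference of that kind between the groups is not ruled out as the source of the trends. For this reason each group below is given with its shift before and after the correction for them, which would also take away an effect that follows abundance or length itself.

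**Figure D2:**
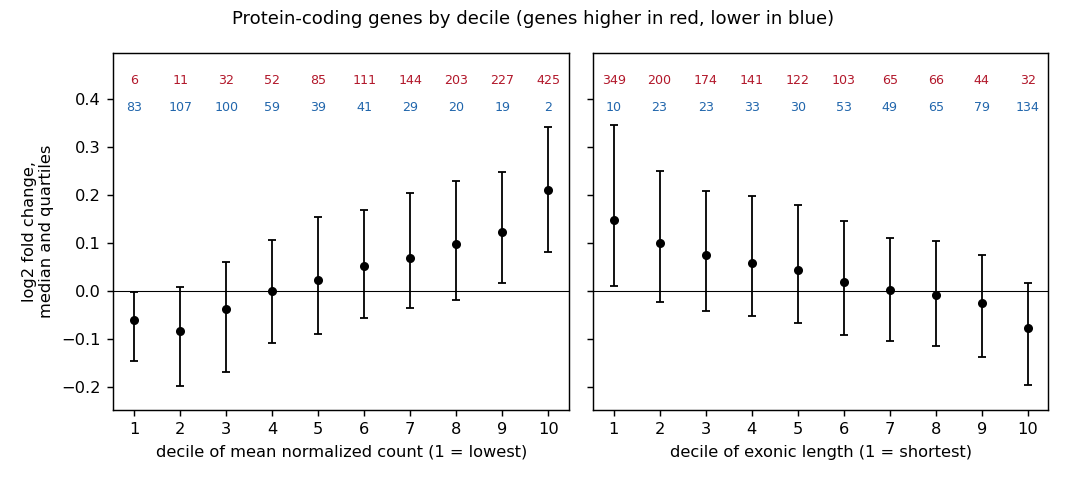
Median log2 fold change of protein-coding genes (point) with quartiles (bars), by decile of mean normalized count on the left and of exonic length on the right, from the lowest or shortest (1) to the highest or longest (10). Red and blue numbers count the genes that rose and fell; the median goes from -0.06 to 0.21 with count and from 0.15 to -0.08 with length.

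Polyamine genes, the first theme of the series title, changed at a few steps. ODC1, the rate-limiting enzyme of polyamine synthesis, rose, with a log2 fold change of 0.67 (SE 0.15, adjusted p = 0.000108) in the authors' deposited table. OAZ1, which encodes the antizyme that holds ornithine decarboxylase down, rose by 0.40 (SE 0.14, adjusted p = 0.00826), and EIF5A, the translation factor that carries the spermidine-derived residue hypusine, by 0.37 (SE 0.12, adjusted p = 0.00720), in the authors' deposited table. These 3 were the only ones of 23 measured members to rise, none fell, and 3 rose when adjusted over the list alone. The decarboxylase AMD1, the synthases SRM and SMS and the catabolic enzyme SAT1 did not pass: the authors' deposited table had AMD1 at 0.08 (SE 0.12, adjusted p = 0.596), SRM at 0.00 (SE 0.12, adjusted p = 0.996), SMS at 0.27 (SE 0.14, adjusted p = 0.0787) and SAT1 at 0.08 (SE 0.11, adjusted p = 0.585). The antizyme inhibitors AZIN1, at 0.09 (SE 0.12, adjusted p = 0.534), and AZIN2, at -0.47 (SE 0.48, adjusted p = 0.0735), did not pass either in the authors' deposited table. As a group the list lay 0.884 z above the other genes (SE 0.377, cameraPR adjusted p = 0.0333), with a median log2 fold change of 0.08. The call ended with a preset correlation of 0.05 (adjusted p = 0.129), and after the correction for count, length and GC the shift was -0.0131 (adjusted p = 0.965).

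The second theme of the title is mitochondria. Of 77 measured nuclear genes of the respiratory chain, 42 rose, none fell and 35 did not pass, and 56 rose when adjusted over the list alone. The authors' deposited table had COX7B at 0.55 (SE 0.14, adjusted p = 0.000520), COX6B1 at 0.48, NDUFB2 at 0.50 and NDUFA6 at 0.57, subunits of complexes IV and I. Their median log2 fold change was 0.31 and the shift 2.55 z (SE 0.256, cameraPR adjusted p = 1.04e-22). The correction left 0.925 (adjusted p = 3.33e-05). Mitochondrial ribosomal proteins moved alike, with 44 of 77 higher and none lower, 56 higher when adjusted over the list alone, and a median of 0.35. MRPL54 stood at 0.73 (SE 0.15, adjusted p = 3.22e-05), MRPL15 at 0.71, MRPL27 at 0.69 and MRPL11 at 0.67 in the authors' deposited table. The list's shift was 2.65 (SE 0.256, cameraPR adjusted p = 2.29e-24), and 1.29 after the correction (adjusted p = 2.01e-09).

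Among genes of mitochondrial protein import and quality control, 13 of 35 rose and none fell, and 20 rose when adjusted over the list alone. The import chaperones TIMM10, at 0.64 (SE 0.17, adjusted p = 0.000662), and TIMM8B, at 0.53, the matrix chaperonin HSPD1, at 0.54, and the prohibitin PHB, at 0.52, were among them in the authors' deposited table. The shift of this list was 2.18 (SE 0.328, cameraPR adjusted p = 1.19e-10), and 0.722 after the correction (adjusted p = 0.0185), where the call ended with a preset correlation of 0.05 (adjusted p = 0.157). The regulators of mitochondrial biogenesis did not pass as a list (shift 0.742, SE 0.355, cameraPR adjusted p = 0.0573, corrected shift 0.176). Of 28 regulators 4 rose and none fell, also when adjusted over the list alone. They were SSBP1 at 0.55 (SE 0.15, adjusted p = 0.00124), TEFM at 0.46, TFB2M at 0.44 and MTERF1 at 0.39 in the authors' deposited table. The coactivator PPARGC1A stood at -0.42 (SE 0.27, adjusted p = 0.0629), NRF1 at 0.28 (SE 0.16, adjusted p = 0.0817) and the mitochondrial DNA packaging factor TFAM at 0.18 (SE 0.15, adjusted p = 0.254) in the authors' deposited table, and none of these passed.

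No mRNA encoded by mitochondrial DNA passed, out of 13 tested by the authors' DESeq2 test, also when adjusted over the list alone; 1 had an unadjusted p under 0.05. MT-ND5 stood at 0.27 (SE 0.17, adjusted p = 0.110), MT-ND4 at 0.14, MT-ND4L at 0.16 and MT-ND6 at 0.11 in the authors' deposited table. The list's shift was 0.278 (SE 0.497, cameraPR adjusted p = 0.673), and -0.817 after the correction (adjusted p = 0.0802). Genes of the mitochondrial genome held only 0.136% of the sum of mean counts, and its mRNAs unevenly, from a mean of 16144 for MT-CO1 to 55.5 for MT-ATP8 in the authors' deposited table. What the counting did with these transcripts is not known, so their values say little about mitochondrial DNA expression.

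**Figure D3:**
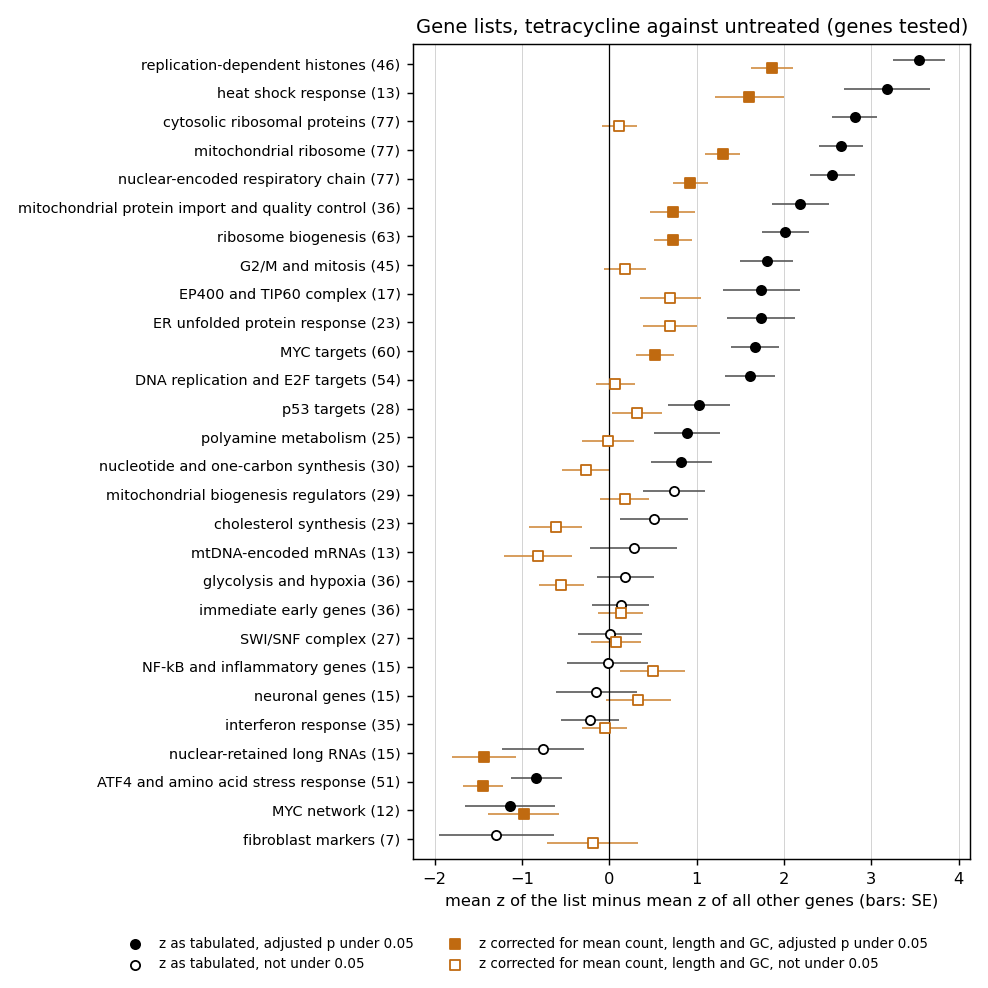
Mean z of each of the 28 testable gene lists minus the mean z of all other genes, with SE (bars); the number of genes tested stands beside each name. Black circles use z as tabulated and orange squares z corrected for mean count, exonic length and GC content; filled symbols passed cameraPR, 15 lists higher and 2 lower as tabulated, 7 higher and 3 lower after the correction.

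MYC mRNA fell, and some of the known targets of the MYC protein rose. MYC stood at -0.53 (SE 0.14, adjusted p = 0.000736) in the authors' deposited table, the only call among 12 members of the MYC network, also when adjusted over the list alone. MLXIPL at -0.26, MNT at -0.31 and MLX at 0.18 in the authors' deposited table did not pass. That list lay lower as a group (shift -1.13, SE 0.515, cameraPR adjusted p = 0.0454, corrected shift -0.981), and the call ended with a preset correlation of 0.05 (adjusted p = 0.116). Of 60 MYC targets, 20 rose, 2 fell and 38 did not pass, with 25 higher and 3 lower when adjusted over the list alone. In the authors' deposited table the nucleolar protein NPM1 stood at 0.59 (SE 0.15, adjusted p = 0.000346), NME1 at 0.66 and LAS1L at 0.52, while the telomerase gene TERT at -1.03 and the nucleoside transporter SLC29A2 at -0.44 were those that fell. The target list, 17 of whose members other lists also hold, had a shift of 1.67 (SE 0.275, cameraPR adjusted p = 4.60e-09). The corrected shift was 0.517 (adjusted p = 0.0492), and the call ended with corrected z and a preset correlation of 0.05 (adjusted p = 0.252) and against random lists matched on count and length (adjusted p = 0.0880).

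Ribosome genes were higher as well. Of 76 cytosolic ribosomal protein genes, 58 rose and none fell, 67 rose when adjusted over the list alone, and the median log2 fold change was 0.34. RPL24 at 0.50 (SE 0.13, adjusted p = 0.00122), RPL6 at 0.48, RPL35 at 0.47 and RPS26 at 0.45 are examples from the authors' deposited table. These are among the most abundant mRNAs, with a median mean count of 26035, and their shift of 2.81 (SE 0.256, cameraPR adjusted p = 4.87e-27) became 0.112 after the correction (adjusted p = 0.738). Against random lists the call held, at 0.935 when matched on mean count (adjusted p = 0.000400) and 0.526 on count and length (adjusted p = 0.00336). That matching is coarse among abundant genes: the top decile of protein-coding genes runs from a mean count of 4132 to 314649. Genes drawn for this list can thus be less abundant than its members, and the matched shifts may keep part of the trend. Ribosome biogenesis factors rose in 22 of 63 cases and fell in none, with 28 higher when adjusted over the list alone. They included EBNA1BP2 at 0.57 (SE 0.13, adjusted p = 0.000178), UTP14A at 0.55, BMS1 at 0.45 and RRN3, an initiation factor of RNA polymerase I, at 0.50 in the authors' deposited table. Their shift was 2.01 (SE 0.271, cameraPR adjusted p = 6.27e-13) and 0.729 after the correction (adjusted p = 0.00271), where the call ended with a preset correlation of 0.05 (adjusted p = 0.130).

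Some genes of the complex that EP400 belongs to rose. Of 17 EP400 and TIP60 complex genes 7 rose, none fell and 10 did not pass, with 7 higher and 1 lower when adjusted over the list alone. ACTL6A stood at 0.56 (SE 0.14, adjusted p = 0.000421), ING3 at 0.56, VPS72 at 0.36 and the helicase RUVBL1 at 0.35 in the authors' deposited table. The shift was 1.74 (SE 0.442, cameraPR adjusted p = 0.000196), and after the correction it was 0.698 and no longer passed (adjusted p = 0.0853). The call also ended against random lists matched on mean count (adjusted p = 0.0840) or on count and length (adjusted p = 0.121). SWI/SNF genes went both ways, with 4 higher, 1 lower and 22 not passing, or 4 and 2 when adjusted over the list alone. SMARCB1 at 0.55 (SE 0.14, adjusted p = 0.000661), BCL7B at 0.43 and BRD7 at 0.33 rose beside ACTL6A, and SMARCC2 at -0.41 (SE 0.16, adjusted p = 0.0164) fell, in the authors' deposited table. That list did not pass (shift 0.0110, SE 0.365, cameraPR adjusted p = 0.976, corrected shift 0.0738), and its median log2 fold change, -0.04, had the opposite sign.

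Chaperone genes were among those that rose. Of 13 heat shock genes 8 rose and none fell, with 10 higher and 1 lower when adjusted over the list alone. The list was written with 16 genes, and HSPA1A, HSPA1B and CRYAB were not found, so the heat shock values leave them out. Beside HSPA8, the cochaperones DNAJA1 at 0.73 (SE 0.14, adjusted p = 5.85e-06) and STIP1 at 0.57 and the HSP110 member HSPH1 at 0.67 rose in the authors' deposited table. The heat shock list had a shift of 3.18 (SE 0.497, cameraPR adjusted p = 5.98e-10), and 1.60 after the correction (adjusted p = 0.000243). In the unfolded protein response of the endoplasmic reticulum 11 of 23 genes rose and none fell, 13 when adjusted over the list alone. SEC61B at 0.63 (SE 0.15, adjusted p = 0.000218), DNAJB11 at 0.59, CALR at 0.42 and HSP90B1 at 0.35 were among them in the authors' deposited table. Their shift was 1.74 (SE 0.390, cameraPR adjusted p = 2.14e-05), and 0.697 after the correction, where it did not pass (adjusted p = 0.0601). It passed against random lists matched on count (0.940, adjusted p = 0.0254) and on count and length (0.787, adjusted p = 0.0283), which allow for no correlation between genes.

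Of 47 genes of the ATF4 and amino acid stress response, 8 fell, 1 rose and 38 did not pass, or 11 and 2 when adjusted over the list alone. The cystine transporter SLC7A11 stood at -1.18 (SE 0.16, adjusted p = 4.38e-11), the glycine transporter SLC6A9 at -1.01, STC2 at -0.74 and asparagine synthetase ASNS at -0.72 in the authors' deposited table. ALDH18A1, a proline synthesis enzyme, was the one that rose, at 0.27 (SE 0.12, adjusted p = 0.0489) in the authors' deposited table. The list lay lower (shift -0.838, SE 0.290, cameraPR adjusted p = 0.00840), and lower still after the correction (-1.45, adjusted p = 2.28e-09). The uncorrected call ended with a preset correlation of 0.05 (adjusted p = 0.116) and with ranks in place of z (adjusted p = 0.0505).

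Histone genes gave the highest shift of any list. Of 39 replication-dependent histone genes 32 rose and none fell, 35 rose when adjusted over the list alone, and the median log2 fold change was 0.52. H3C1 stood at 0.89 (SE 0.13, adjusted p = 3.94e-09), H4C1 at 0.74 and H4C4 at 0.72 beside H2AC21 in the authors' deposited table. Reads of near-identical histone copies may have been split between them, so single values are uncertain. The shift was 3.54 (SE 0.300, cameraPR adjusted p = 7.45e-31) and 1.86 after the correction (adjusted p = 1.68e-13), and these are short RNAs, with a median exonic length of 645 bases.

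Other proliferation genes rose in smaller numbers. Of 54 DNA replication and E2F targets 12 rose and none fell (17 adjusted over the list alone), among them RRM1 at 0.58 (SE 0.14, adjusted p = 0.000231), CCNE2 at 0.57, FEN1 at 0.48 and CDC6 at 0.44 in the authors' deposited table. Of 44 genes of G2/M and mitosis 15 rose and none fell (21 adjusted over the list alone), among them DLGAP5 at 0.52 (SE 0.14, adjusted p = 0.000839), ANLN at 0.46, NDC80 at 0.47 and CCNB1 at 0.48 in the authors' deposited table. Both lists passed, with shifts of 1.61 (SE 0.285, cameraPR adjusted p = 4.78e-08) and 1.80 (SE 0.303, cameraPR adjusted p = 8.35e-09). After the correction neither did, at 0.0695 (adjusted p = 0.848) and 0.176 (adjusted p = 0.647). Of 28 p53 targets 3 rose and none fell, also when adjusted over the list alone: RPS27L at 0.60 (SE 0.17, adjusted p = 0.00135), TRIAP1 at 0.53 and AEN at 0.38 in the authors' deposited table, where PPM1D at 0.26 (SE 0.13, adjusted p = 0.0756) did not pass. The p53 list's shift of 1.03 (SE 0.360, cameraPR adjusted p = 0.00889) became 0.319 after the correction (adjusted p = 0.432), and its call also ended with a preset correlation of 0.05 (adjusted p = 0.0785).

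Glycolysis and hypoxia genes split, with 7 higher and 4 lower of 36, or 8 and 5 when adjusted over the list alone. The glycolytic enzymes ENO1 at 0.54 (SE 0.13, adjusted p = 0.000166), TPI1 at 0.52 and GAPDH at 0.35 rose in the authors' deposited table. The hypoxia-responsive NDRG1 at -0.63 (SE 0.13, adjusted p = 1.80e-05), VEGFA at -0.39, PDK1 at -0.31 and the kinase PDK3 at -0.34 were those that fell in the authors' deposited table. The list as a whole did not pass (shift 0.183, SE 0.328, cameraPR adjusted p = 0.673, corrected shift -0.552). Of 23 cholesterol synthesis genes 2 rose and 1 fell, also when adjusted over the list alone. NSDHL at 0.41 (SE 0.15, adjusted p = 0.0132) rose, INSIG1 at -0.43 (SE 0.14, adjusted p = 0.00690) fell and FDFT1 at 0.23 (SE 0.12, adjusted p = 0.0938) did not pass in the authors' deposited table. That list had a shift of 0.511 (SE 0.390, cameraPR adjusted p = 0.254, corrected shift -0.616). Of 29 genes of nucleotide and one-carbon synthesis only UMPS rose, at 0.44 (SE 0.13, adjusted p = 0.00346), also when adjusted over the list alone, while PPAT at 0.27, AHCY at 0.23 and IMPDH2 at 0.24 did not pass in the authors' deposited table. The nucleotide list's shift of 0.823 (SE 0.351, cameraPR adjusted p = 0.0333) went to -0.269 after the correction (adjusted p = 0.517), and its call ended with a preset correlation of 0.05 (adjusted p = 0.138).

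Immune and immediate early genes did not move as groups. Of 29 interferon response genes B2M rose, at 0.37 (SE 0.16, adjusted p = 0.0264), and IFI44L fell, at -1.15 (SE 0.35, adjusted p = 0.00178), while HERC5 at 0.28 did not pass in the authors' deposited table. Adjusted over the list alone, 0 rose and 1 fell, and the shift was -0.224 (SE 0.331, cameraPR adjusted p = 0.635, corrected shift -0.0555). CD274, which encodes PD-L1, had a mean count of only 9.50 and a log2 fold change of -0.04 with no adjusted p in the authors' deposited table. Of 9 NF-kB and inflammatory genes NFKB2 fell, at -0.42 (SE 0.23, adjusted p = 0.0445), and NFKBIA at 0.15, NFKB1 at 0.14 and BIRC3 at -0.06 did not pass in the authors' deposited table. None passed when adjusted over the list alone, and the shift was -0.0201 (SE 0.466, cameraPR adjusted p = 0.976, corrected shift 0.493). Of 30 immediate early genes 3 rose and none fell, also when adjusted over the list alone. They were MCL1 at 0.41 (SE 0.15, adjusted p = 0.0122), ID3 at 0.37 and DUSP6 at 0.53, and FOSB at -0.68 (SE 0.61, adjusted p = 0.0513) did not pass, in the authors' deposited table. The list's shift was 0.128 (SE 0.328, cameraPR adjusted p = 0.780, corrected shift 0.130).

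The list named nuclear-retained long RNAs, which also holds structural RNAs, had 2 higher and 1 lower of 14, or 2 and 3 when adjusted over the list alone. FTX, a nuclear long RNA, fell, at -0.37 (SE 0.17, adjusted p = 0.0355), and NEAT1, the paraspeckle RNA, did not pass at -0.55 (SE 0.54, adjusted p = 0.0619) in the authors' deposited table. The members that rose were RN7SL1, the RNA of the signal recognition particle, at 0.39 (SE 0.13, adjusted p = 0.0134), and the small nucleolar RNA host SNHG1 at 0.37 in the authors' deposited table. Both are counted in the shift of the list. RN7SL1 has near-identical copies and alone held 2.69% of the sum of mean counts in the authors' deposited table. Outside the list, the long RNA XIST fell, at -0.61 (adjusted p = 0.00124) and a mean count of 129137 in the authors' deposited table. The list did not pass (shift -0.762, SE 0.466, cameraPR adjusted p = 0.143), but it passed after the correction (shift -1.44, adjusted p = 0.000445).

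Markers of other cell types were low in count or did not pass. Not passing between the groups does not tell whether RNA of such cells was present. Some markers were not low in count, such as STMN3 at a mean of 1951 and FBN1 at 545 in the authors' deposited table. Of the 16 blood cell markers, leukocyte and haemoglobin genes, 3 were in the table, CD8A, CD14 and HBA1, with mean counts of 11.1, 5.85 and 2.92 in the authors' deposited table and none with an adjusted p. No fibroblast marker passed of 6 and no neuronal gene of 11, by the authors' DESeq2 test or adjusted over the list alone, where 1 and 3 had an unadjusted p under 0.05. COL3A1 stood at -0.39 (SE 0.28, adjusted p = 0.0767), COL1A1 at -0.14, FBN1 at -0.09 and PDGFRA at -0.09, and of the neuronal genes SYT1 at -0.47 (SE 0.30, adjusted p = 0.0549), CHGB at 0.37, STMN3 at 0.23 and SYP at 0.19, in the authors' deposited table. The shifts were -1.30 (SE 0.658, cameraPR adjusted p = 0.0716, corrected -0.193) for the fibroblast list and -0.149 (SE 0.466, cameraPR adjusted p = 0.808, corrected 0.332) for the neuronal list.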

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

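Of the alternatives below, the correction of z for mean count, exonic length and GC content, the random lists matched on count and length, and the count over protein-coding genes only were chosen after the data were seen; the others were set before the data were examined. No paired analysis was possible because no values per library were used here. For the same reason a refit with edgeR or DESeq2, a replicate block and leaving out each library were not run. Depth per library is not known, and genes under a mean normalized count of 41.2 have no adjusted p.

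The number of changed genes kept within 1.5 times its value with other minimum counts (from 1535 to 1904 genes) and with protein-coding genes only (1858). Centring on the median gene, and a log2 fold change of at least 0.25, removed no call and so say nothing on stability. An adjusted p under 0.01 gave 758 genes, 548 higher and 210 lower, and one under 0.1 gave 942 lower. Bonferroni left 143 (101 higher, 42 lower), because the threshold is stricter. A log2 fold change of at least 1 left 53, 5 higher and 48 lower, or 9.43% higher, since the deep changes are falls. The empirical null left 3 genes, 3 higher and 0 lower (100% higher), because it divides z by 1.85. The corrected z left 298, 151 higher and 147 lower (50.7%); 252 of them were among the genes reported.

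Of 28 lists, 17 passed as reported, from 12 to 18 under the alternatives set beforehand, 10 with corrected z, 6 with corrected z and a correlation of 0.05, and 11 against lists matched on count and length. The respiratory chain and mitochondrial ribosome lists stayed higher and passed under every alternative. The polyamine list no longer passed with a correlation of 0.05 (shift 0.884, adjusted p = 0.129), log2 fold changes (0.0926, in log2 units, 0.0990), means of at least 100 (0.802, 0.107), a protein-coding background (0.728, 0.107) or lists matched on count (0.158, 0.665). Its sign turned with corrected z (-0.0131, 0.965, and 0.974 at 0.05) and matched on count and length (-0.112, 0.810). The mitochondrial regulators passed with a correlation of 0 (0.742, 0.0300) or no minimum count (0.783, 0.0323), and import and quality control did not with corrected z at 0.05 (0.722, 0.157). The mtDNA-encoded mRNAs turned to -0.817 with corrected z (adjusted p = 0.0802, or 0.215 at 0.05) and -0.666 matched on both (0.161). Other calls ended as well, and those given here are not all of them. Against lists matched on count these were EP400 and TIP60 (0.832, 0.0840), p53 targets (0.564, 0.121), DNA replication (0.478, 0.0799) and G2/M (0.498, 0.0799). With ranks they were the MYC network (adjusted p = 0.0526) and ATF4 (0.0505), and with log2 fold changes the MYC network (0.0912) and nucleotide synthesis (0.112). The p53 call also ended with means of at least 100 (adjusted p = 0.107), and that of the MYC network with corrected z at 0.05 (0.144). Fibroblast markers passed with ranks (0.0336), and nuclear-retained RNAs passed when matched on count (-1.82, 0.00218). For these lists the cause was not tested.

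In all 33 list values changed sign, 25 passing in neither setting, 8 only as reported and 0 in both; the cause was not tested. With corrected z, at either correlation, these were NF-kB 0.493, glycolysis -0.552, cholesterol -0.616, nucleotide synthesis -0.269 and neuronal genes 0.332. Matched on count they were NF-kB 0.533, glycolysis -0.563, cholesterol -0.416, nucleotide synthesis -0.298, SWI/SNF -0.455 and neuronal genes 0.0573. Matched on count and length they were NF-kB 0.502, glycolysis -0.474, cholesterol -0.580, nucleotide synthesis -0.256, SWI/SNF -0.0227, neuronal genes 0.120 and DNA replication -0.0437. With means of at least 100, glycolysis was at -0.118 and SWI/SNF at -0.185, and with a protein-coding background immediate early genes were at -0.0290 and SWI/SNF at -0.146. Of the named genes, 57 kept their sign and their call, or lack of one, with corrected z. A further 74 kept their sign but stopped passing, and 105 stopped passing with the empirical null. The 74 are not listed here, so single rises and falls rest on the deposited adjusted p. With corrected z 14 changed sign with none called either way: BIRC3 0.771, AHCY -0.0494, SMS -0.0758, TFAM -0.319, COL1A1 0.755, SRM -0.732, AMD1 -0.772, SAT1 -2.41, PDGFRA 0.606, AZIN1 -0.439, FBN1 0.582, IMPDH2 -0.375, EP400 0.295, MT-ND4 -0.0609.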

Other observations

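Of the tests in this part, those of gene families, the trend tests by single ribosomal or respiratory list, the matching on count and length, and the ATF4 test were chosen after the results were seen. Genes that share a symbol stem were grouped into families, and each family was tested as the lists were, with the adjustment over all families. The PSMD and COMMD families were among those called higher. Of 13 PSMD genes, which encode the regulatory particle of the proteasome, 9 rose and none fell. PSMD1 stood at 0.74, PSMD14 at 0.58 and PSMD8 at 0.53 in the authors' deposited table. The shift was 3.42 z (cameraPR adjusted p = 3.08e-10) and 1.89 after the correction for count, length and GC. Of 10 COMMD genes, whose proteins act in endosomal sorting, 6 rose and none fell, with a shift of 2.99 and a corrected shift of 2.38. COMMD9 stood at 0.75, COMMD1 at 0.63 and COMMD5 at 0.47 in the authors' deposited table.

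Collagen and semaphorin genes lay lower. Of 26 collagen genes 5 fell and none rose, with COL13A1 at -1.05, COL27A1 at -0.64 and COL5A1 at -0.63 in the authors' deposited table. Semaphorins had 4 that fell and 1 that rose, with SEMA3G at -1.28, SEMA3B at -0.97 and SEMA3C at 0.54 in the authors' deposited table. The shifts were -1.59 and -1.78, and after the correction -0.438 and -0.739, where neither passed. Over all families of at least 10 genes, 168 in number, 31 were higher and 11 lower, and 6 and 0 after the correction.

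The respiratory chain, mitochondrial ribosome and cytosolic ribosomal protein lists were all higher, and 3 explanations were weighed. The first is the trend of fold change with count, length and GC content. Its prediction was written before the corrected lists were tested, but after the data were seen. It was that at least 1 of the lists would fall under a shift of 0.5 or not pass. The cytosolic ribosomal list kept a shift of only 0.112 after the correction, so this prediction was met. Over random lists matched on count and length it kept 0.526 (permutation adjusted p = 0.00336). That matching is coarse among abundant genes, and the correction would also take away an effect that follows abundance. For this list the tests therefore cannot tell. The respiratory chain kept 0.925 and the mitochondrial ribosome 1.29, so the trend as modelled did not take up their whole shift. Exonic length counts all annotated exons and not the expressed transcript, and the splines were additive. A remaining trend is therefore not ruled out for those lists either. The second is more unspliced or intergenic RNA in the untreated libraries. Antisense, sense intronic and lincRNA genes together lay 0.0253 above protein-coding genes of the same count (permutation p = 0.00380). That is what was written beforehand for the absence of such an excess. With length matched too they lay at -0.0354 (permutation p = 0.0001, the smallest that 10000 draws can give). The classes also differed. Matched on count, the 445 antisense genes lay at 0.0452, the 344 lincRNA genes at 0.0112 and the 64 sense intronic genes at -0.0388. With length matched too these were -0.0164, -0.0455 and -0.113. The sign thus depended on the matching and, matched on count alone, on the class, so the test cannot tell. The biological explanation, a response to EP400NL or to the antibiotic, which are not separable here, was not tested and stays open.

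The MYC target list was higher while MYC mRNA fell. If the trend with count, length and GC were the cause, the corrected shift would be under 0.5 or not pass; it was 0.517 (SE 0.217, adjusted p = 0.0492), too close to that bound to tell. The prediction was written before the corrected list was tested, but after the data were seen. Lower MYC mRNA as feedback on a higher MYC activity, through EP400NL or otherwise, is a biological explanation that was not tested and stays open.

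Tetracyclines can block mitochondrial translation, which is known to raise ATF4 targets. A response of that kind would put the ATF4 list above 0, and it lay at -0.838 (SE 0.290, adjusted p = 0.00840, and 0.116 with a preset correlation of 0.05). The call also ended with ranks in place of z (adjusted p = 0.0505), but the list lay lower and passed with corrected z (-1.45, and adjusted p = 0.000470 at a correlation of 0.05) and against lists matched on count (-1.40) or on count and length (-1.47). The list shows no net rise, but a lowering of the same genes by EP400NL could offset one, and the antibiotic and EP400NL came together in these libraries, so the test cannot tell. An effect of EP400NL on ATF4 targets was not tested and stays open.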
